A study of Oncorhynchus mykiss with 6 samples.

How the data were processed

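Gill tissue of rainbow trout was sampled in 2 groups of 3, control and IHNV infection at 48 hours, and libraries were made from total RNA. Groups and replicate numbers were taken from the sample labels. The processed data were 1 table of 72602 genes with 1 FPKM column per sample, and all 6 columns were used. The FPKM values (fragment counts scaled by transcript length and by the mapped total of the library) were computed by the authors and deposited with 2 decimals. Per the submitters' processing notes, Bowtie2 2.2.8 and TopHat2 2.1.1 were used; the genome build, the annotation version, the tool that made the FPKM values and its treatment of strand and multiply mapped reads are not given in the sources used here. Per the file headers, the same table holds the authors' fold ratio, its log2 value and a p-value and q-value per gene; the authors' test is not named. These columns were used only to compare calls. The table also carries GO and KEGG terms per gene, which were used for the enrichment test.

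Gene IDs were matched to an NCBI RefSeq table of assembly USDA_OmykA_1.1, used for biotypes and gene lengths. Gene symbols and descriptions came with the deposited values. The lengths enter the check of snoRNA genes and the bins of gene span below, and may differ from those behind the FPKM values. Of the 72602 genes, 69936 matched by gene ID and the rest by symbol. No coordinates are given, since the build behind the deposited values is not named. Rainbow trout carries many near-identical gene copies, and values of paralogs can be split or shared by the authors' counting.

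FPKM is not a count and depth could not be recovered. Among 220 snoRNA genes of at most 100 bases, values went down to 0.01 FPKM and 7.29% of values were under 0.1 FPKM, too low to be whole reads of genes that short at usual depths. Precision therefore rests on the spread between the 3 libraries of a group. Among genes with a mean of at least 1 FPKM, at most 168 values were identical between any pair of libraries, so none was taken as deposited again.

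Values were taken as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 libraries (23370) were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is on the log2(FPKM + 1) scale and understates the change of genes with low values. The SD is over libraries on the FPKM scale and the SE is from limma. Adjusted p-values without another tool named are from limma, and those of lists are from camera, adjusted over 24 lists. Python 3.11.15 with pandas 2.3.3 prepared the tables and matplotlib 3.10.9 drew the plots.

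The design, the 24 gene lists, the naming rule and the alternatives below were fixed before the data were examined. Named genes were, per direction, the 12 with the largest log2 change among called genes whose groups did not overlap, with a mean of at least 5 FPKM in the higher group and a descriptive name, keeping 1 per description; and per list the 2 called members with the largest change in each direction and the most abundant member. Lists were matched by symbol or name pattern, so some took in loci that their heading does not describe; these are named where they led a list, and a version without them was added later. List tests were limma's camera with a preset correlation of 0.01 (a competitive test), camera with an estimated correlation, and fry. Terms of 10 to 500 tested genes were tested with Fisher's exact test, one-sided, against the tested genes that carry a term of that kind (21972 for GO and 10003 for KEGG), with adjustment within each kind and direction.

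Alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at a mean of 5 FPKM, median-of-ratios and quantile scaling, eBayes without trend and robust eBayes, a minimum log2 change of 1, the replicate number as a block, and leaving out each library in turn.

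The fit was tested on simulated data for the IHNV and control comparison, with 23370 genes drawn from the real means and SDs and 50 genes changed per size and direction. It recovered 88% of genes raised by 1 on the log2 scale and 82% of those lowered by 1, and 96% of genes changed by 2 in either direction, with 8 unchanged genes called. A list and a term planted in the simulated comparison were both recovered. The changed genes were drawn from genes with a control level above 2 FPKM. Genes varied independently and the median of all genes was not shifted. These results therefore do not cover genes at lower levels, correlated genes or a broad shift.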

Results

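Gene expression was measured by RNA sequencing in gill tissue of rainbow trout (Oncorhynchus mykiss) at 48 hours after infection with infectious hematopoietic necrosis virus (IHNV), a negative-strand RNA rhabdovirus of salmonid fish, and in control gill. There were 3 control and 3 IHNV libraries. The deposited table gave FPKM for 72602 annotated genes, of which 41809 were above 0 in at least 1 library. Summed FPKM ranged from 531519 to 560456 per library. Genes above 0 numbered 37145 to 37936 in the controls and 35839 to 36161 after IHNV. The number of reads per library was unknown, so no counting interval is given and the precision of each value rests on the 3 libraries per group. The labels do not say that libraries came from separate fish, and p-values therefore measure the spread between these samples, which may be technical. Pearson correlations of log2 values were 0.969 to 0.985 among controls, 0.985 to 0.988 among IHNV libraries and 0.908 to 0.936 between the groups. The first principal component held 73.5% of the variance and separated the groups, and the second held 11.04% and separated control replicate 3 from the other controls.

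Control replicate 3 contained transcripts that the other 5 libraries nearly lacked. The somatostatin-1A-like locus LOC110490058 was at 656 FPKM there and at most 0.79 FPKM elsewhere, preproinsulin 1 (LOC100136702) at 463 against at most 0.69 FPKM, and chymotrypsin A-like LOC110510477 at 311 against at most 0.38 FPKM. All 10 loci matched by pancreatic hormone names and 24 of 30 matched by digestive enzyme names that reached 1 FPKM in any library were at least 10 times higher in this library than in each other library.

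**Figure D1:**
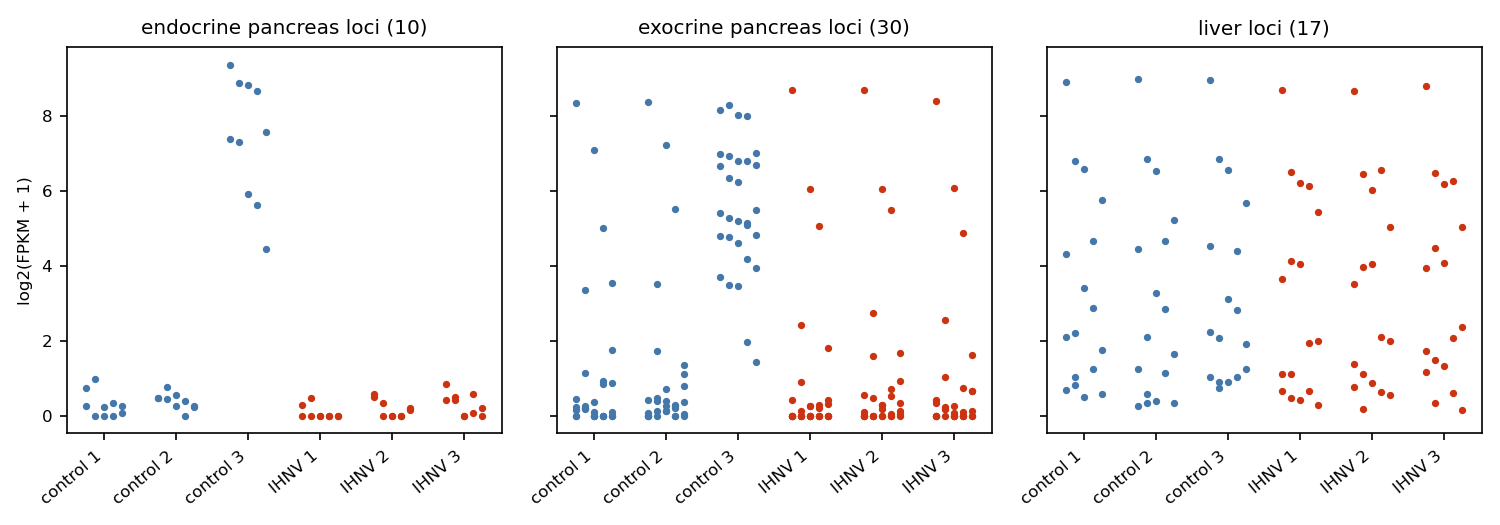
Expression of loci matched by name patterns for pancreatic hormones (10), pancreatic digestive enzymes (30) and liver proteins (17) in each of the 6 libraries, as log2(FPKM + 1), with 1 point per locus and control libraries in blue and IHNV libraries in red. The enzyme pattern also took in a trypsin inhibitor, and the liver pattern took in loci that are not liver proteins, such as RNA-binding protein-like loci. The hormone loci stand apart in control replicate 3 alone, where LOC110490058 reached 656 FPKM; 16 of the 17 loci of the liver pattern reached 1 FPKM in another library as well.

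The comparison of IHNV with control gill addressed how the gill transcriptome differed at 48 hours after infection. Interferon-induced antiviral genes, heat shock genes and phagocyte markers were higher after IHNV, and genes of DNA replication, hemoglobins and collagens were lower. The erythrocyte and extracellular matrix lists were not called by camera with an estimated correlation (adjusted p = 0.386 and 0.314). Of 23370 genes tested, 2892 were higher and 8654 lower at an adjusted p under 0.05 in the limma fit, with 13302 at an unadjusted p under 0.05. A log2 change of at least 1 in size was found in 814 of the higher and 473 of the lower genes, and one of at least 2 in 287 higher and 8 lower genes. These counts are on the log2(FPKM + 1) scale, which understates changes of genes with low values, where lower calls outnumbered higher ones. The groups did not overlap for 60.7% of the genes, against 10% by chance.

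The direction of the majority depended on the scaling. On the deposited FPKM scale the median log2 fold change of all genes tested was -0.19, and 75% of called genes were lower. After median-of-ratios rescaling the median was 0.05, with 5767 genes higher and 3490 lower (62.3% higher), and after quantile normalization it was -0.06, with 3573 higher and 5132 lower (41% higher). A total of 2573 genes were called higher and 2967 lower under all 3 scalings. At a log2 change of at least 1 in size, median-of-ratios gave 1155 higher and 174 lower genes, against 814 and 473 on the deposited scale. The calls also depended on expression level. With the genes ranked by mean FPKM into 10 bins of 2337, 104 were higher and 1020 lower in the lowest bin, and 682 were higher and 530 lower in the highest. Relative to the all-gene median of -0.19, the list medians given below lay at 2.05 for interferon-induced effectors, 0.77 for heat shock genes, -0.64 for the cell cycle, -0.63 for erythrocyte markers and -0.57 for the extracellular matrix. They lay at -0.21 for antioxidant enzymes, -0.33 for endothelial markers, -0.09 for T cell markers and -0.01 for epithelial markers.

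**Figure D2:**
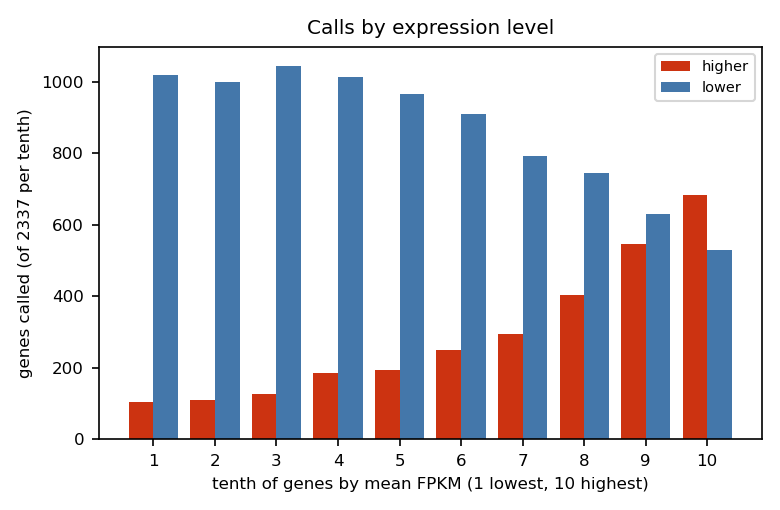
Number of genes called higher (red) or lower (blue) after IHNV in 10 bins of the 23370 tested genes ranked by mean FPKM, with 2337 genes per bin. Lower calls outnumber higher calls in every bin but the highest, with 682 higher and 530 lower; the deposited scaling was used, and the split differs under the other scalings.

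The largest rises included members of the interferon-induced list, such as vig1, ifit9 and cmpk2. The ubiquitin-like protein gene ublp rose from 6.69 ± 0.233 to 1095 ± 82.2 FPKM (mean ± SD, n = 3 per group, as for all FPKM values given), a log2 fold change of 7.15 ± 0.07 (SE) with an adjusted p of 9.48e-09 by limma. The polyubiquitin-like LOC118936268 rose from 4.72 ± 0.45 to 694 ± 37.4 FPKM. Viperin (vig1), a radical SAM enzyme with antiviral activity, rose from 4.71 ± 0.323 to 392 ± 51.8 FPKM (adjusted p = 4.42e-08). Another viperin locus, LOC110498119, rose from 0.58 ± 0.149 to 84.3 ± 15.03 FPKM. Virus-induced genes of the same set were LOC100135997 (VHSV-induced protein-5), from 7.54 ± 1.17 to 462 ± 34.3 FPKM, and ifit9, from 15.4 ± 0.863 to 690.0 ± 25.6 FPKM. The set was completed by sacsin-like LOC110505631 (3.87 to 175 FPKM), receptor-transporting protein 2-like LOC110529481 (15.02 to 496 FPKM) and PML-like LOC110521242 (23.3 to 662 FPKM). It also held asteroid homolog 1-like LOC110535305 (3.72 to 122 FPKM), cmpk2, a mitochondrial nucleotide kinase (6.97 to 191 FPKM), and the Mx GTPase locus LOC110494493 (4.097 to 121 FPKM). Each of these 12 was higher in 3 of 3 IHNV libraries than in every control, as the naming rule required. Reads of near-identical copies, such as the viperin loci, may have been split by the authors' counting.

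**Figure D3:**
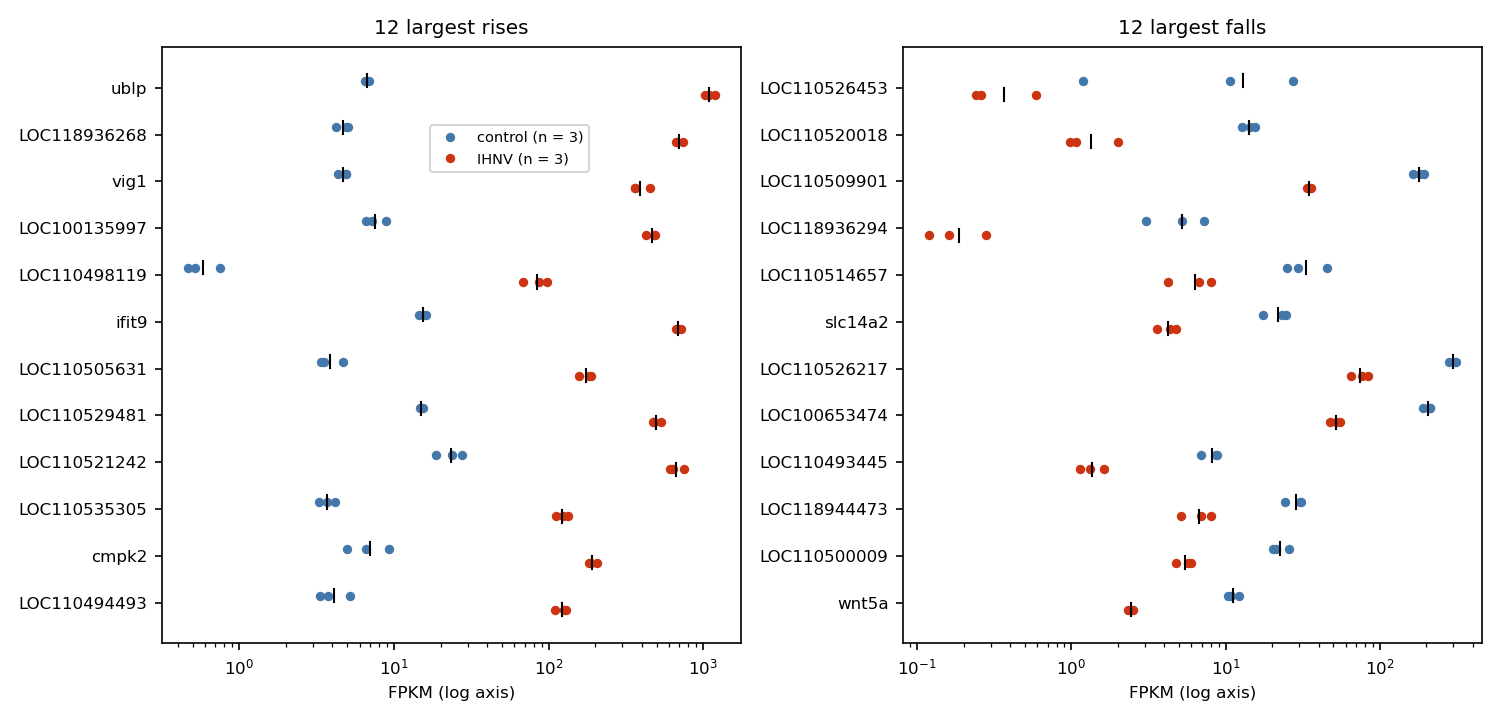
FPKM of the 12 genes with the largest rises (left) and the 12 with the largest falls (right) on log axes, with 1 point per library, black bars for group means, controls in blue and IHNV in red (n = 3 each). In every gene shown the groups do not overlap, as the naming rule required. The gene ublp moves from 6.69 to 1095 FPKM and eosinophil peroxidase-like LOC110509901 from 180.1 to 34.9 FPKM.

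Of 80 interferon-induced antiviral effector loci tested, 62 rose and 4 fell (64 and 4 adjusted over the list alone), with a median log2 fold change of 1.85. The camera test with its preset correlation gave an adjusted p of 2.99e-43, and the adjusted p was 0.0467 with an estimated correlation. Members that fell were a guanylate-binding protein 1-like locus, LOC110501949 (from 55.5 ± 6.32 to 28.4 ± 3.54 FPKM), and a poly(ADP-ribose) polymerase 14-like locus, LOC110531552 (from 22.2 ± 2.53 to 12.7 ± 0.719 FPKM). Of 44 loci for sensors of viral RNA and their signalling, 27 rose and 2 fell (27 and 3 adjusted over the list alone; adjusted p = 1.49e-17 by camera and 0.0467 with an estimated correlation). Among them dhx58, an RNA helicase of the RIG-I family, rose from 9.89 ± 0.562 to 157 ± 14.5 FPKM. The interferon regulatory factor 3-like LOC110497044 rose from 11.2 ± 1.0 to 161 ± 21.5 FPKM, and irf1b, the most abundant, rose from 113 ± 5.04 to 207 ± 10.2 FPKM. This list had taken in TRIM25-like loci of a large fish family, and those that fell, LOC110493686 (adjusted p = 0.0416) and LOC110538123 (adjusted p = 0.0323), belong to it. Of the gene LOC110493686 the call ended without control replicate 1 (adjusted p = 0.109), 2 (0.0596) or 3 (0.101) or IHNV replicate 1 (0.0531), and with the replicate block (0.062) and the filter at a mean of 5 FPKM (0.0503). Of the gene LOC110538123 it ended without control replicate 1 (adjusted p = 0.098) or 3 (0.0968) or IHNV replicate 1 (0.0858), 2 (0.0651) or 3 (0.063), and neither locus was called under the other scalings or without the expression filter. Without the TRIM25-like family 14 of 19 loci rose and 0 fell.

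Of 36 loci for interferons and JAK-STAT signalling, 22 rose and 4 fell (22 and 6 adjusted over the list alone). The camera adjusted p of 1.36e-10 became an adjusted p of 0.0805 with an estimated correlation. The receptor locus LOC110501424 (interferon alpha/beta receptor 2) rose from 3.6 ± 0.9796 to 80.4 ± 16.96 FPKM, stat1b from 12.7 ± 0.831 to 113 ± 9.89 FPKM and the STAT locus LOC110520020 from 31.04 ± 2.62 to 224 ± 24.3 FPKM. The receptor 1a-like locus LOC110520635 fell from 2.84 ± 0.222 to 1.68 ± 0.247 FPKM and JAK2-like LOC110523953 from 9.71 ± 0.4598 to 7.18 ± 0.2401 FPKM; the first was not called after quantile normalization and the second not after median-of-ratios rescaling.

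Chemokine genes moved both ways: 19 of 55 loci rose and 17 fell (19 and 19 adjusted over the list alone). The homing chemokine ccl19a.1 rose from 8.59 ± 1.26 to 222 ± 8.32 FPKM, the virus-induced CXC chemokine LOC100135977 from 0.643 ± 0.595 to 21.9 ± 6.67 FPKM and C-C motif chemokine 4-like LOC110536450 from 66.7 ± 10.9 to 427 ± 23.8 FPKM. C-C motif chemokine 13-like loci fell, LOC110514657 from 33.3 ± 10.7 to 6.33 ± 1.93 FPKM and LOC110515790 from 7.35 ± 1.16 to 1.46 ± 0.665 FPKM. The list's median was -0.06 and its mean 0.337, so that they differ in sign; camera called it higher (adjusted p = 0.00322; adjusted p = 0.129 with an estimated correlation). In camera, chemokines, that call ended under median-of-ratios (adjusted p = 0.116) and quantile scaling (adjusted p = 0.121).

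Of 24 loci for inflammatory cytokines and mediators, 7 rose and 5 fell. Interleukin-1 beta rose at LOC110536401 (from 5.82 ± 0.767 to 21.4 ± 5.27 FPKM) and LOC100136024 (from 3.01 ± 0.194 to 11.9 ± 2.03 FPKM). The interleukin-17 family genes il17a/f1 and il17d fell, from 2.13 ± 0.634 to 0.627 ± 0.218 and from 5.98 ± 1.11 to 3.26 ± 1.303 FPKM, and the call of the gene il17d ended under both other scalings and without control replicate 2 (adjusted p = 0.0677), IHNV replicate 2 (0.0677) or IHNV replicate 3 (0.0656). The most abundant member, il4/13a, was at 25.1 ± 1.65 FPKM in controls and 17.8 ± 5.32 FPKM after IHNV (adjusted p = 0.0606), and was called lower after quantile normalization (adjusted p = 0.0437) and without IHNV replicate 1 (adjusted p = 0.0186). The cytokine list's camera adjusted p was 0.0416, with a negative median of -0.06 and a positive mean of 0.141, and the adjusted p was 0.348 with an estimated correlation. The call also ended in camera, inflammatory cytokines and mediators, without control replicate 1 (adjusted p = 0.0887) or IHNV replicate 1 (adjusted p = 0.0565), after median-of-ratios rescaling (adjusted p = 0.146) and with the filter at a mean of 5 FPKM (adjusted p = 0.248).

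Markers of macrophages and neutrophils rose at 23 of 37 loci and fell at 3 (25 and 3 adjusted over the list alone; camera adjusted p = 5.89e-14; adjusted p = 0.0467 with an estimated correlation). The matrix metalloproteinase gene mmp9 rose from 34.3 ± 11.3 to 237 ± 33.6 FPKM, collagenase 3 (LOC100136017) from 407 ± 25.6 to 1404 ± 154 FPKM and the antimicrobial peptide cathelicidin LOC118936275 from 5.39 ± 0.453 to 31.1 ± 5.78 FPKM. Lysozyme g (LOC110517266) fell from 35.9 ± 8.14 to 19.3 ± 2.57 FPKM and the NADPH oxidase subunit-like nox1 from 2.103 ± 0.206 to 1.37 ± 0.144 FPKM, the latter not called under either other scaling. Of 20 complement loci, 6 rose and 3 fell. The risers with the largest changes, LOC118936357 (from 1.25 ± 0.3396 to 9.18 ± 3.77 FPKM) and LOC110538203 (from 2.33 ± 0.494 to 13.2 ± 1.62 FPKM), are C1q-like proteins and not components of the complement cascade. Complement factor D (LOC100653474), the serine protease of the alternative pathway, fell from 205 ± 12.5 to 51.7 ± 3.801 FPKM, and C4-like LOC110503832, not called after median-of-ratios rescaling, from 6.01 ± 0.578 to 3.82 ± 0.778 FPKM. The most abundant member, c1qb, was at 136 ± 18.9 FPKM in controls and 137 ± 9.08 FPKM after IHNV. The complement list's camera adjusted p of 0.0352 became 0.15, as an adjusted p with an estimated correlation, and 0.828 without the C1q-like loci, and in camera, complement, it was 0.0831 without control replicate 2 and 0.0587 without IHNV replicate 3. It was 0.101 under median-of-ratios and 0.415 under quantile scaling, and 0.392 with the filter at a mean of 5 FPKM.

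Genes of MHC class I antigen presentation rose at 16 of 39 loci and fell at 6 (17 and 6 adjusted over the list alone; camera adjusted p = 1.86e-07; adjusted p = 0.21 with an estimated correlation). The transactivator nlrc5 rose from 3.65 ± 0.2098 to 10.3 ± 0.749 FPKM, tapasin-related LOC110503634 from 11.2 ± 1.01 to 28.1 ± 5.29 FPKM and beta-2-microglobulin-like LOC110491889, the most abundant, from 1155 ± 31.2 to 1649.8 ± 68.6 FPKM. Endoplasmic reticulum aminopeptidase 2 (LOC110536151) fell from 10.9 ± 1.21 to 5.65 ± 0.691 FPKM. The list had also taken in class II loci, and without them 16 of 36 rose and 3 fell. In the list for MHC class II antigen presentation 17 of 34 loci rose and 4 fell (camera adjusted p = 2.79e-06; adjusted p = 0.0805 with an estimated correlation), but the largest rises were CD209 lectin genes, LOC110537264 (from 12.3 ± 1.44 to 75.4 ± 2.92 FPKM) and cd209 (from 10.5 ± 3.48 to 61.4 ± 1.28 FPKM). Without lectins 3 of 16 rose and 4 fell (camera adjusted p = 0.432). The class II alpha chain LOC118940033 fell from 35.2 ± 3.17 to 15.2 ± 0.45 FPKM. The class II transactivator LOC110511347 fell from 3.31 ± 0.405 to 1.92 ± 0.459 FPKM but was not called under either other scaling. The most abundant class II locus, LOC110494409, was at 1039 ± 119 FPKM in controls and 1075 ± 99.9 FPKM after IHNV and was called higher after median-of-ratios rescaling.

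The lists of lymphocyte markers were not called by camera. The fry test, which sets a list against no change and not against other genes, called 4 lists lower that camera did not, on a scale with an all-gene median of -0.19. They were T cell and cytotoxic cells (adjusted p = 0.0376), antioxidant enzymes (0.00321), endothelial and pillar cells (0.00177) and epithelial and mucous cells (0.00395). Of 53 B cell and immunoglobulin loci 10 rose and 8 fell (10 and 7 adjusted over the list alone; camera adjusted p = 0.171). A polymeric immunoglobulin receptor-like locus, LOC110521598, rose from 2.01 ± 0.0723 to 9.74 ± 1.595 FPKM and CD22-like LOC110488629 from 0.55 ± 0.03 to 2.35 ± 0.282 FPKM. The B cell kinase gene btk fell from 23.5 ± 2.05 to 12.5 ± 1.78 FPKM and another receptor-like locus, LOC110528822, from 3.6 ± 0.997 to 1.48 ± 0.183 FPKM. The most abundant member, xbp1, was at 64.9 ± 4.87 FPKM in controls and 69.3 ± 1.16 FPKM after IHNV and was called higher after median-of-ratios rescaling. CD22-like loci carry names of a lectin family that is not specific to B cells, and in camera, B cell markers and immunoglobulins, the list was called higher without the expression filter (adjusted p = 0.00527). Of 32 T cell and cytotoxic cell loci 4 rose and 13 fell (5 and 13 adjusted over the list alone; camera adjusted p = 0.831). Perforin-1-like LOC118936277 rose from 4.35 ± 1.23 to 10.8 ± 1.41 FPKM and granzyme B-like LOC110520655 from 9.59 ± 2.07 to 23.1 ± 7.39 FPKM. NK-lysin-like LOC110505297 fell from 2.103 ± 0.145 to 0.377 ± 0.269 FPKM and granzyme-like si:ch211-212d10.1 from 14.03 ± 0.9796 to 6.23 ± 1.04 FPKM. The T cell transcription factor gene gata3 was at 46.7 ± 3.94 FPKM in controls and 51.1 ± 1.95 FPKM after IHNV and was called higher after median-of-ratios rescaling.

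Heat shock and unfolded protein response genes rose at 47 of 69 loci and fell at 2, with a median log2 fold change of 0.58 (camera adjusted p = 1.67e-24; adjusted p = 0.0467 with an estimated correlation). The chaperone HSP 90-alpha-like LOC110529844 rose from 9.93 ± 3.09 to 96.7 ± 7.13 FPKM and hsp70b from 1.19 ± 0.204 to 12.03 ± 1.37 FPKM. The transcription factor gene hsf1 fell from 5.14 ± 0.885 to 2.97 ± 0.497 FPKM. The ATF-4-like LOC110508391 was called lower at 215 ± 6.53 FPKM in controls and 176 ± 14.9 FPKM after IHNV, but its log2 fold change of -0.29 turned to 0.01 after median-of-ratios rescaling, and the call of the gene LOC110508391 ended without control replicate 1 (adjusted p = 0.0501). The constitutive chaperone hspa8 was at 2217 ± 13.6 FPKM in controls and 2058 ± 42.8 FPKM after IHNV (adjusted p = 0.109); of the gene hspa8 the adjusted p was 0.0498 with the filter at a mean of 5 FPKM. Of 44 apoptosis and cell death loci 15 rose and 9 fell (camera adjusted p = 8.79e-04; adjusted p = 0.0724 with an estimated correlation). The risers included the caspase-8 regulator LOC110501891 (from 5.57 ± 0.466 to 14.2 ± 0.681 FPKM), caspase-3-like LOC110516770 (from 4.15 ± 0.452 to 10.1 ± 1.24 FPKM) and the inflammasome adapter LOC110516260 (from 91.9 ± 2.35 to 176 ± 2.34 FPKM). BAX-like LOC110521871 fell from 7.34 ± 0.455 to 4.11 ± 0.728 FPKM and caspase-2-like LOC110509281 from 6.01 ± 0.366 to 3.39 ± 0.0153 FPKM. In the apoptosis list 23 loci were higher and 2 lower after median-of-ratios rescaling, and 14 and 7 after quantile normalization.

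**Figure D4:**
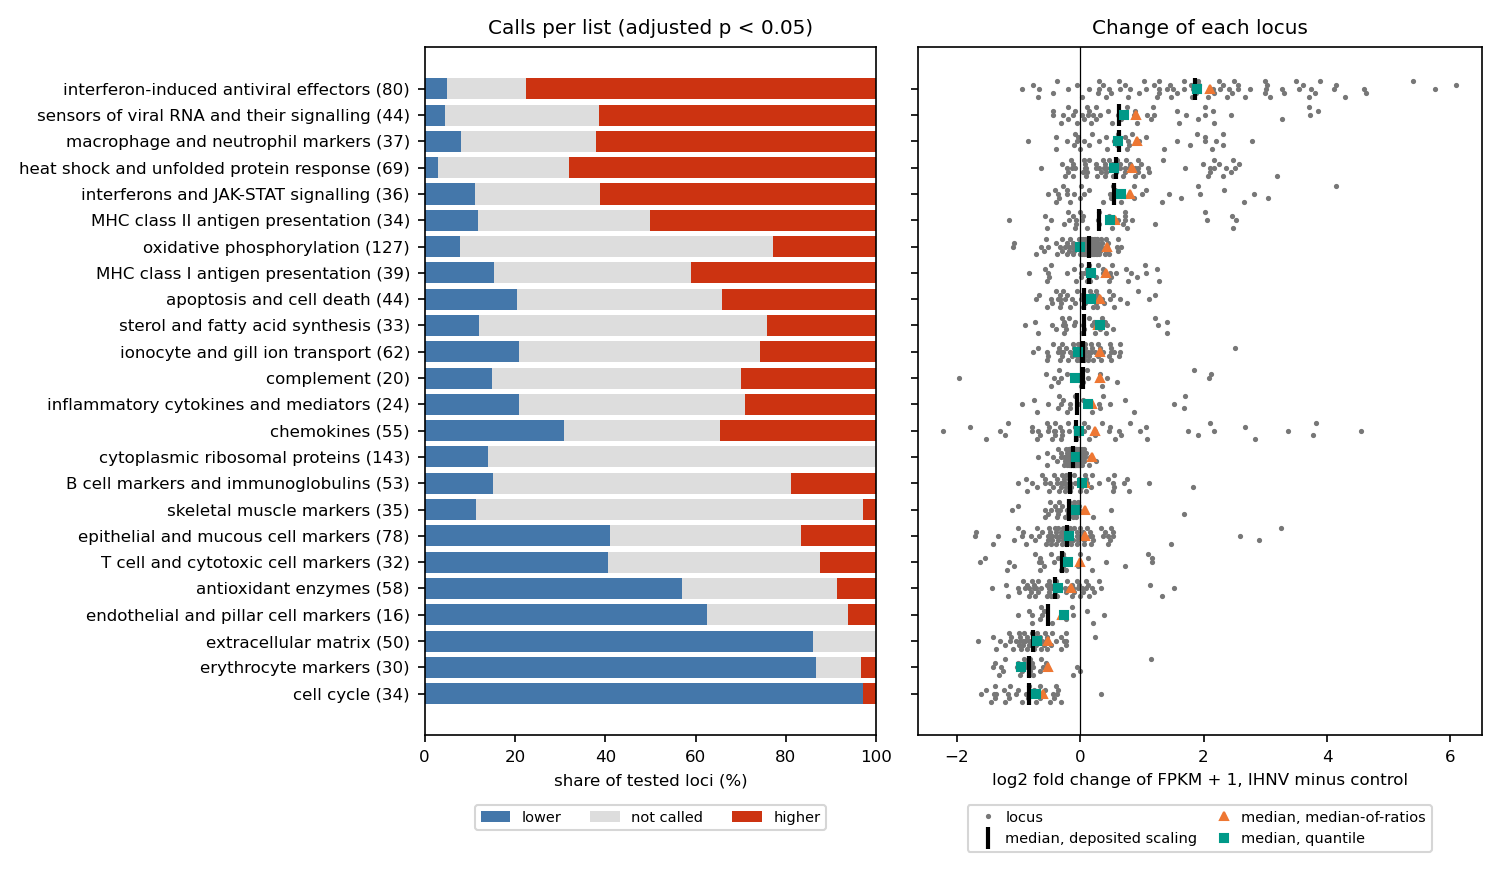
Left, share of the tested loci of each of 24 gene lists that were called lower (blue), higher (red) or not called (grey), with the number tested in brackets; right, the log2 fold change of each locus (grey points) on the deposited scaling and the list's median under each of 3 scalings. On the deposited scaling the interferon-induced list lies highest, with 62 of 80 loci called higher, and the cell cycle list lowest, with 33 of 34 called lower and a median of -0.83 against -0.82 for erythrocyte markers, which lie lowest after quantile normalization. The median of ribosomal proteins changes sign between scalings.

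Cell cycle genes fell at 33 of 34 loci, with a median log2 fold change of -0.83 (camera adjusted p = 8.18e-10; adjusted p = 0.0467 with an estimated correlation), and 25 of the 33 were also called lower after median-of-ratios rescaling. The DNA replication licensing genes LOC110493296 (mcm2-like) and mcm3 fell from 14.1 ± 0.2098 to 4.02 ± 0.6899 and from 21.1 ± 0.991 to 6.69 ± 0.729 FPKM, and the sliding clamp gene LOC110525832 (proliferating cell nuclear antigen), the most abundant member, from 96.0 ± 6.65 to 53.8 ± 2.49 FPKM. The remaining locus, aurkaip1, an aurora kinase A-interacting protein that is no cell cycle kinase, was called higher at 21.7 ± 2.51 FPKM in controls and 27.5 ± 3.83 FPKM after IHNV with an adjusted p of 0.04995. Of the gene aurkaip1 the call ended without control replicate 1 (adjusted p = 0.109), control replicate 3 (0.145), IHNV replicate 1 (0.132) or IHNV replicate 2 (0.0901), after quantile normalization, and with the other pseudocounts and filters or no trend.

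Genes of the extracellular matrix fell at 43 of 50 loci and rose at 0 (45 and 1 adjusted over the list alone), with a median of -0.76; the camera adjusted p was 1.05e-08 and the adjusted p was 0.314 with an estimated correlation. Type I collagen col1a1 fell from 49.7 ± 3.89 to 15.1 ± 0.915 FPKM, collagen VI LOC110531056 from 28.5 ± 2.49 to 10.1 ± 0.295 FPKM and sparc, the most abundant, from 428 ± 17.2 to 275 ± 32.3 FPKM. Endothelial and pillar cell markers fell at 10 of 16 loci and rose at 1 (camera adjusted p = 0.0942, not called). In camera, endothelial and pillar cell markers, the list was called lower after median-of-ratios rescaling (adjusted p = 0.0209) and without the expression filter (adjusted p = 0.033). The angiopoietin receptor genes LOC110521820 (Tie-1-like) and tek fell from 2.97 ± 0.19 to 0.99 ± 0.252 and from 4.69 ± 0.176 to 2.22 ± 0.0321 FPKM. Von Willebrand factor-like vwf fell from 39.6 ± 2.96 to 24.9 ± 1.54 FPKM. The gene egfl7 rose from 8.08 ± 1.03 to 10.8 ± 0.822 FPKM, and the call of the gene egfl7 ended without IHNV replicate 2 (adjusted p = 0.0563).

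Erythrocyte markers fell at 26 of 30 loci and rose at 1, with a median of -0.82 (camera adjusted p = 3.38e-05; adjusted p = 0.386 with an estimated correlation). All 21 hemoglobin loci fell. The most abundant, hemoglobin beta-4 (LOC100136291), fell from 1392 ± 198 to 886 ± 135 FPKM but was not called after median-of-ratios rescaling, hemoglobin alpha-like LOC110486351 fell from 143 ± 35.1 to 53.5 ± 8.38 FPKM and hemgn, described in the annotation as a GATA-type zinc finger protein, from 10.5 ± 2.86 to 3.29 ± 0.937 FPKM. Of the 26 loci 21 were also called lower after median-of-ratios rescaling. The riser, erythroid membrane-associated protein-like LOC110523368 (from 69.3 ± 5.57 to 155 ± 21.4 FPKM), carries a name of the butyrophilin-related family. Hemoglobin copies are near-identical, so their single values are uncertain.

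Of 58 antioxidant enzyme loci 33 fell and 5 rose (35 and 5 adjusted over the list alone), with no call of the list as reported (camera adjusted p = 0.0585); in camera, antioxidant enzymes, the adjusted p was 0.0398 without control replicate 1, 0.0259 without control replicate 3 and 0.0124 without IHNV replicate 1, and it was 1.17e-05 after quantile normalization, 0.0139 without the expression filter, 0.0177 with the filter at a mean of 5 FPKM and 0.0292 with the replicate block, each time lower. Median-of-ratios rescaling gave 13 loci higher and 18 lower with no call of the list (camera adjusted p = 0.0858), and quantile normalization gave 4 and 32. The glutathione synthesis gene gclc fell from 40.5 ± 2.79 to 17.03 ± 1.23 FPKM and microsomal glutathione S-transferase 3-like LOC110530534 from 12.95 ± 1.01 to 4.21 ± 1.01 FPKM. Heme oxygenase-like loci rose, LOC110485518 from 9.26 ± 1.72 to 28.1 ± 0.827 FPKM and LOC118936555 from 13.4 ± 1.19 to 34.9 ± 3.15 FPKM. The most abundant member, nqo1, fell from 383 ± 34.5 to 275 ± 18.6 FPKM and was not called after median-of-ratios rescaling.

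Epithelial and mucous cell genes moved both ways, with 13 of 78 loci higher and 32 lower (13 and 33 adjusted over the list alone; camera adjusted p = 0.831). The majority depended on the scaling, with 22 higher and 14 lower after median-of-ratios rescaling and 13 and 27 after quantile normalization. Mucin-2-like loci rose, LOC110533168 from 6.49 ± 0.638 to 71.5 ± 16.6 FPKM and LOC110496830, of biotype misc_RNA, from 0.143 ± 0.127 to 7.46 ± 0.231 FPKM. The type I keratin genes zgc:92380 (keratin 18-like) and k13 fell from 235 ± 21.5 to 71.7 ± 9.54 and from 295 ± 4.37 to 91.2 ± 0.376 FPKM, while keratin 13-like LOC110493627, the most abundant, rose from 766 ± 43.3 to 973 ± 46.02 FPKM. Of 62 loci for ionocytes and gill ion transport 16 rose and 13 fell (camera adjusted p = 8.79e-04; adjusted p = 0.0467 with an estimated correlation), but the median was 0.05 and turned to -0.03 after quantile normalization, which also ended the camera call. In camera, ionocyte and gill ion transport, the adjusted p was then 0.482, and 0.0544 with the filter at a mean of 5 FPKM. Of the 62 loci 35 were higher and 2 lower after median-of-ratios rescaling, and 14 and 12 after quantile normalization. A V-type proton ATPase subunit a-like locus, LOC110488719, rose from 4.09 ± 0.332 to 27.99 ± 1.18 FPKM and a sodium/potassium ATPase beta subunit, LOC110527208, from 223 ± 21.1 to 351 ± 28.2 FPKM. The ammonium transporter genes rhag and rhcg fell from 63.2 ± 2.73 to 36.7 ± 1.21 and from 438 ± 15.5 to 305 ± 35.4 FPKM, rhcg not being called after median-of-ratios rescaling, and another beta subunit, LOC110490065, fell from 4.14 ± 0.352 to 2.23 ± 0.502 FPKM. The gene rhag is also a member of the erythrocyte list, so its fall is not particular to gill ion transport.

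Of 127 oxidative phosphorylation loci 29 rose and 10 fell (19 and 7 adjusted over the list alone). The counts became 88 higher and 3 lower after median-of-ratios rescaling, and 8 and 11 after quantile normalization. The camera adjusted p of 6.71e-10 became an adjusted p of 0.348 with an estimated correlation, and the median of 0.15 became -0.01 after quantile normalization (adjusted p = 0.46 in camera, oxidative phosphorylation). Cytochrome c oxidase 7A2 loci rose, LOC110522088 from 15.7 ± 1.41 to 25.4 ± 4.02 FPKM and LOC110503623 from 8.7 ± 1.502 to 13.9 ± 2.12 FPKM; the subunit 4 isoform 2 locus LOC110492636 and the subunit 8B-like si:dkey-85n7.8 fell from 7.69 ± 0.855 to 3.11 ± 0.815 and from 164 ± 10.6 to 77.7 ± 1.23 FPKM. The most abundant, LOC110537530, was at 375 ± 9.82 FPKM in controls and 409.6 ± 22.7 FPKM after IHNV and was called higher after median-of-ratios rescaling. Of 143 cytoplasmic ribosomal protein loci 0 rose and 20 fell (0 and 1 adjusted over the list alone), and the direction depended on the scaling, with 23 called higher and 1 lower after median-of-ratios rescaling. The 40S protein SA-like LOC110486515, a pseudogene in the annotation, fell from 6.22 ± 0.5103 to 3.54 ± 0.805 FPKM and S27-like LOC110524214 from 15.9 ± 2.79 to 10.6 ± 1.05 FPKM, the latter not called after median-of-ratios rescaling. The most abundant, rpl13a, was at 1577 ± 7.43 FPKM in controls and 1452 ± 53.1 FPKM after IHNV, and the gene rpl13a was called lower without IHNV replicate 1 (adjusted p = 0.0449); in camera, cytoplasmic ribosomal proteins, the same omission moved the adjusted p from 0.347 to 0.00716. The list was called higher by camera after median-of-ratios rescaling (adjusted p = 3.98e-05) and lower after quantile normalization (adjusted p = 0.00885) and with the filter at a mean of 5 FPKM (adjusted p = 0.0177).

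Of 33 loci for sterol and fatty acid synthesis 8 rose and 4 fell (camera adjusted p = 0.0051; adjusted p = 0.348 with an estimated correlation). In camera, sterol and fatty acid synthesis, the adjusted p was 0.0873 with the filter at a mean of 5 FPKM. The leading risers are cholesterol 25-hydroxylase genes, whose product 25-hydroxycholesterol restrains sterol synthesis and has antiviral activity: ch25h rose from 4.32 ± 0.519 to 13.2 ± 1.64 FPKM, LOC110498991 from 17.1 ± 3.23 to 41.2 ± 9.13 FPKM and LOC110498990 from 4.25 ± 2.66 to 12.8 ± 6.49 FPKM. The call of the gene LOC110498990 ended without control replicate 2 (adjusted p = 0.0702), control replicate 3 (0.0682) or IHNV replicate 1 (0.0619) and with robust eBayes (0.0659). Acyl-CoA desaturase-like LOC110502614 fell from 17.3 ± 1.82 to 8.86 ± 0.448 FPKM. Skeletal muscle markers, included as a sign of other tissue in the samples, rose at 1 and fell at 4 of 35 loci (1 and 2 adjusted over the list alone; camera adjusted p = 0.558). The most abundant, LOC100136006 (skeletal alpha-actin 2-like), was at 33.0 ± 15.9 FPKM in controls and 28.6 ± 4.45 FPKM after IHNV. Parvalbumin LOC110499196 rose from 0.0533 ± 0.0924 to 2.42 ± 0.762 FPKM, and parvalbumin-7-like LOC110538011 and the calcium pump LOC110537826 fell from 3.09 ± 2.103 to 0.75 ± 0.108 and from 32.5 ± 1.38 to 23.04 ± 0.845 FPKM; the call of the gene LOC110538011 ended without IHNV replicate 2 (adjusted p = 0.0542) and after quantile normalization.

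In lists for which no second count is given, the counts adjusted over the list alone were equal to those over all genes. With its preset correlation camera called 17 of 24 lists, and with an estimated correlation 6, namely interferon-induced effectors, viral RNA sensors, macrophage and neutrophil markers, heat shock, ionocyte transport and cell cycle. These 6 share an adjusted p of 0.0467 in camera with an estimated correlation. It comes from the highest of their unadjusted p-values, 0.0117 for the cell cycle list, so the 6 calls stand or fall together. A larger correlation does not account for every lost or weakened call. The estimated correlation was -0.047 for complement, -0.002 for ionocyte transport and 0.007 for apoptosis, each below the preset 0.01. Their unadjusted camera p still rose, from 0.0234 to 0.0688, from 4.76e-04 to 0.0114 and from 4.56e-04 to 0.0211. The forms of camera thus differ in more than the correlation used. The medians of the chemokine, cytokine, complement, B cell, epithelial, muscle, ribosomal, ionocyte and oxidative phosphorylation lists changed sign between scalings. For the B cell, epithelial and muscle lists the median and mean were negative while camera, which compares a list with all other genes, gave the direction higher; none of the 3 was called.

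The largest falls by the naming rule included genes for an iron transporter-like protein, a granule peroxidase and proteases. Solute carrier 40 member 1-like LOC110520018, a homolog of the cellular iron exporter ferroportin, fell from 14.2 ± 1.33 to 1.35 ± 0.559 FPKM (log2 fold change -2.72 ± 0.16 SE; adjusted p = 2.29e-05 by limma), and ferric-chelate reductase 1 LOC110500009 from 22.4 ± 3.096 to 5.44 ± 0.633 FPKM. Eosinophil peroxidase-like LOC110509901, a granule peroxidase, fell from 180.1 ± 14.98 to 34.9 ± 1.13 FPKM (adjusted p = 8.11e-07). The astacin-type protease LOC110526217 (low choriolytic enzyme-like) fell from 299.8 ± 16.7 to 74.9 ± 9.203 FPKM, the urea transporter slc14a2 from 21.8 ± 3.702 to 4.23 ± 0.621 FPKM and the signalling ligand wnt5a from 11.1 ± 0.999 to 2.44 ± 0.0907 FPKM. Others were LOC118936294, a molybdopterin synthase subunit-like locus (5.18 to 0.187 FPKM), LOC110493445, annotated as the RNA helicase DDX17 (8.14 to 1.36 FPKM), LOC118944473, a lncRNA in the annotation that carries the name small inducible cytokine A13 (28.5 to 6.697 FPKM), and the chemokine LOC110514657 and complement factor D (LOC100653474) given above. Trypsin-3-like LOC110526453, a digestive protease, was called lower with values of 10.7, 1.18 and 27.2 FPKM in control replicates 1, 2 and 3 and at most 0.59 FPKM after IHNV (adjusted p = 0.0251); control replicate 3 is the library with pancreatic transcripts, and the call of the gene LOC110526453 ended without it (adjusted p = 0.0503), without control replicate 1 (adjusted p = 0.071) and without IHNV replicate 1 (0.0661), 2 (0.0634) or 3 (0.0507). It also ended with robust eBayes (adjusted p = 0.0915) and without the expression filter (adjusted p = 0.0503).

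Annotated terms passed the one-sided Fisher's exact test for 75 GO and 21 KEGG terms among higher genes and 126 GO and 32 KEGG terms among lower genes. This test takes each locus as an independent draw. Gene copies and genes of the same term can vary together, and its p-values are then too small. The extracellular matrix list, for example, had an estimated correlation of 0.361 in camera. Of the terms enriched among higher genes, defense response to virus held 27 higher (against 6.16 by chance) and 13 lower genes of 51 tested (adjusted p = 1.18e-09). Cellular response to heat held 14 higher and 2 lower genes of 19 (adjusted p = 2.48e-07). The RIG-I-like receptor pathway held 45 higher and 26 lower genes of 125 (adjusted p = 2.71e-08). Cytokine-cytokine receptor interaction held 115 higher genes of 343, against 48.4 by chance, and also 94 lower ones. Of those among lower genes, KEGG DNA replication held 48 lower (against 20.7 by chance) and 0 higher genes of 58 (adjusted p = 4.16e-11). Homologous recombination held 39 lower and 0 higher genes of 47 (adjusted p = 1.37e-09). Collagen trimer held 47 lower and 0 higher genes of 61 (adjusted p = 1.47e-07). Chromatin binding held 141 lower and 16 higher genes of 225 (adjusted p = 3.73e-11) and the Wnt signaling pathway 155 lower and 23 higher genes of 297 (adjusted p = 9.00e-08). Without control replicate 3, 2449 genes were called higher and 6512 lower, and 8698 genes had the same call as with it.

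The authors' deposited table marked 1226 genes as up and 3117 as down after IHNV, all with a log2 fold change of at least 1 in size and a q-value of at most 0.05. Of the genes marked in the authors' deposited table, 1680 lay below the expression filter used here. Above that filter, 1025 of the 1042 genes marked up in the authors' deposited table were called higher here and 1613 of the 1621 marked down were called lower, with 0 called in the opposite direction. The calls here used the same FPKM values and had no minimum fold change, so the 2 thresholds are unlike. With a minimum log2 change of 1 on the log2(FPKM + 1) scale, 814 genes were higher and 473 lower here. These counts cannot be set against the authors' 1226 and 3117. The expression filter removed more of the genes marked down, since 1621 of 3117 lay above it, against 1042 of 1226 marked up. The log2(FPKM + 1) scale also understates changes of genes with low values. The counts here therefore do not show that large changes were mainly rises.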

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

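The version of the lists without loci that their heading does not describe was chosen after seeing the data; all other alternatives were planned. The number of genes higher after IHNV was 2892 as reported and moved to 5767 with median-of-ratios rescaling and to 814 with a minimum log2 change of 1. The number of genes lower was 8654 as reported and moved to 3490 with median-of-ratios rescaling, 5132 with quantile normalization, 3557 with the filter at a mean of 5 FPKM (fewer genes tested, 11618) and 473 with the minimum log2 change. The 3490 lower genes after median-of-ratios rescaling were all among the 8654, the 2892 higher genes were all among the 5767, and 0 genes were called in opposite directions under any setting. Lists called numbered 17 as reported, 6 with an estimated correlation, 18 by fry and 15 without the misplaced loci. Terms passing fell from 254 to 147 with the filter at 5 FPKM. Beyond the construction of a filter or a threshold, the cause was not tested. The other pseudocounts, no filter, no trend and robust eBayes gave 2781 to 2981 higher and 8579 to 10489 lower genes.

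Leaving out 1 library at a time gave 2449 to 2674 higher genes, 6512 to 7677 lower genes, 16 to 18 lists, 228 to 287 terms and 114 to 118 of the 121 named calls. Samples with the same replicate number did not deviate together (correlations -0.072, -0.067 and 0.028), so no pairing by number was seen. With 3 libraries per group, these correlations cannot exclude it. The replicate block gave 2682 higher and 7502 lower genes, 18 lists, 294 terms and 120 named calls. Over named genes and settings, 1859 results kept direction and side of the threshold, 58 lost their call, 8 gained one and 1 reversed. The reversed gene LOC110508391, an ATF-4-like locus, had a log2 fold change of -0.29 as reported and 0.0105 with median-of-ratios rescaling (not called). That rescaling divides each library by 1 factor, and other genes moved similarly, such as nqo1 from -0.4754 to -0.1768 and xbp1 from 0.0976 to 0.3927. Over lists and settings, 365 results kept their side, 28 lost and 13 gained a call, and 1 reversed: cytoplasmic ribosomal proteins were lower in camera as reported (adjusted p = 0.347, not called) and higher with median-of-ratios rescaling (adjusted p = 3.98e-05), which raised the median of all genes from -0.19 to 0.05 and that of the list from -0.109 to 0.19. Depth was unknown, and the 3 libraries per group limit which small changes can be called; the median SE of a log2 fold change was 0.102.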

Other observations

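The tests of sample splits, of pancreas loci, of organ loci low elsewhere, of a single scale factor and of erythrocyte loci were chosen after the results they bear on had been seen, and the genes in this and the next paragraph outside the naming rule, and f2 below, were chosen after their values were seen. Hepcidin (LOC100135935), the peptide hormone that acts on ferroportin, rose from 0.28 ± 0.14 to 5.32 ± 0.301 FPKM (mean ± SD, n = 3 per group; limma adjusted p = 6.57e-06), while transferrin receptor tfr1a was at 11.5 ± 0.865 FPKM in controls and 11.5 ± 0.467 FPKM after IHNV.

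Several enriched terms lay outside the fixed lists. Their p-values also take each locus as independent and may be too small. NAD+ ADP-ribosyltransferase activity held 29 higher (against 5.92 by chance) and 6 lower genes of 49 (adjusted p = 1.01e-11, Fisher's exact test), with gig2e rising from 36.03 ± 2.05 to 404 ± 63.6 FPKM. The proteasome core complex held 21 higher and 0 lower genes of 44 (adjusted p = 1.10e-06), among them the immunoproteasome subunit gene psmb9a, from 88.8 ± 11.8 to 157 ± 8.61 FPKM. C-X-C chemokine receptor genes rose at 8 and fell at 0 of 10 loci (adjusted p = 1.22e-04), LOC110495453 from 1.65 ± 0.855 to 26.2 ± 5.24 FPKM. Lower genes were enriched in xenobiotic metabolism by cytochrome P450 (32 lower and 3 higher genes of 53, adjusted p = 0.00245) and in the Fanconi anemia pathway of DNA repair (43 lower and 2 higher genes of 61, adjusted p = 8.10e-07).

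The 6 samples can be split into groups of 3 in only 10 ways, too few for a share under 0.05. In 1 of the 10, the real one, the fit called 2892 genes higher and 8654 lower, and the highest of the others called 1 gene in a direction. Terms passing numbered 254 in the real split and at most 0 in the others. Lists called by camera with its preset correlation numbered 17 in the real split and up to 16 in the others. Every other split places control and IHNV libraries in both groups. The difference between control and IHNV then adds to the spread within groups and partly remains between them. Counts in those splits are therefore not a level set by chance, for genes, terms or lists.

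Control replicate 3 held pancreatic transcripts. Liver, gut or kidney RNA was argued against as their source, since 0% of 25 loci matched by such names were at least 10 times higher in it than in each other library; 18 of the 25 were low enough elsewhere for 10 times their level to lie within the median hormone locus in it (175.4 FPKM), and of 109 loci under 1 FPKM in each other library 1 reached 1 FPKM in it (prothrombin gene f2, 1.36 FPKM), against at most 1 in any other library by the same count. Some of the 25 loci are not proteins of these organs, such as RNA-binding protein-like loci, and stomach and kidney rest on 1 locus each. Also argued against was a mislabelled infected sample, since the interferon-induced list's median log2(FPKM + 1) differed by 0.013 from the mean of the other controls and by -2.09 from the IHNV mean. Pancreas RNA stays open as a candidate source: 80% of 30 loci matched by digestive enzyme names met the same criterion, 7 of the 30 reaching 1 FPKM in another library too; hormone loci, by a name pattern narrowed after insulin-like growth factor loci were seen to match it, summed to 2605 FPKM there and 0.99 to 3.47 FPKM elsewhere, and enzyme loci to 2448 and 442 to 544 FPKM. No biological explanation was tested; 0 of the 10 hormone loci and 4 of the 30 enzyme loci were called between groups, and none of those 4, trypsin-3-like LOC110526453 among them, met the criterion.

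Most called genes were lower on the deposited scale. A single scale factor stays open for the majority, since median-of-ratios, with 1 factor per library, turned it to 62.3% higher, although that scaling centres the genes by construction; such a factor leaves unexplained that the median log2 fold change differed by 0.325 between 10 bins of mean FPKM. The share of summed FPKM taken by genes called higher was 13.2% ± 0.318 in controls and 26.4% ± 0.665 after IHNV (SD, n = 3). This alone would shift all other genes by -0.238 on the log2 FPKM scale, or 122.6% of the all-gene median. That median is on the log2(FPKM + 1) scale, where the same shift is smaller for genes with low values, so the percentage is too high. The bound set beforehand was met only on these unlike scales. As totals are nearly fixed, the share must balance the falls whatever their cause. The change in share therefore cannot be told apart from a real fall of many genes. Like a single factor, it leaves the spread between bins unexplained, with a median of -0.309 in the lowest and 0.016 in the highest. Matched on mean FPKM, medians over 4 bins of annotated gene span differed by 0.101, between the bounds set for and against a length effect, so that one stays open as well. A wide fall of transcripts after infection stays among the candidate explanations, untested.

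Erythrocyte genes were lower after IHNV. The scaling was argued against as the whole cause, since the list's median lay -0.573 from the all-gene median under median-of-ratios and -0.904 under quantile scaling, where 21 and 26 of the 26 loci were still called lower. Also argued against was the sharing of reads between hemoglobin copies, since FPKM summed over the hemoglobin loci was lower in 3 of 3 IHNV libraries, at 0.552 of the control mean. Less blood in the sampled tissue stays open: the median of the 9 other erythrocyte loci lay 0.1 above that of the 21 hemoglobin loci, as such a loss may predict, although only 5 of the 9 were called lower. A loss of erythrocytes or of their transcripts through infection would give the same values and was not tested.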
